A study of Homo sapiens with 6 samples.

How the data were processed

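RNA sequencing values of 6 HUVEC libraries were used, 3 from cells transfected with miR-483 and 3 from cells transfected with 8OH-G miR-483, with RNA taken on day 2, per the labels. The submitters' processing notes name cutadapt, STAR, HTSeq, DESeq2 and the genome build hg19, with no versions, parameters or order. Each deposited file holds 1 column of decimal values for 20792 rows. Neither the labels nor the file headers name the unit. It was inferred to be FPKM, fragments scaled for gene length and library size, by the authors: column totals of 1396537 to 1687283 exceed what TPM or CPM can reach, and the values of uniquely named nuclear genes times gene length summed to nearly the same total in every library (1132 to 1167 in units of 1000). If the unit were another length-scaled one, fold changes within a gene would be read in the same way.

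The test fixed before the data were examined was a quasi-likelihood count test, with limma on log2(value + 1) as the stated fallback for normalized values. Because the files hold no counts, the fallback was used. Low values were checked for whole-read steps: 20.6% of 980 low genes lay within 0.05 log2 of a whole-read ratio at the best of 200 depth ratios, against a median of 16.9% over all ratios. Whole reads were therefore not recovered and read depth is unknown, so precision is given as the SD over 3 libraries or as a standard error, with no counting interval.

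Names occurred once on 17588 rows. The other 3204 rows shared 748 names. In 5 libraries each repeated name had a single value on all of its rows, but in miR-483 replicate 1 this held for 14 of the names. Repeated names were left out and added back, at the highest value per name and library, as an alternative. For 708 of the names this value in replicate 1 lay within 0.5 log2 of that in replicate 2. In addition, 24 rows had names turned into dates. MT-ND4L and MT-ATP8 had implausibly high values, and mitochondrial rows made up 71.3% to 76.6% of the total FPKM, against which nuclear values were not rescaled. Strand, multi-mapped reads and replicate origin are not given in the sources used here, so paralogs and overlapping genes are uncertain.

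Genes with at least 1 FPKM in at least 3 libraries were tested (12216). Values were log2-transformed with a pseudocount of 1 and fitted with limma 3.58.1 in R 4.3.3 (trend and robust variance shrinkage, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes from limma are 8OH-G miR-483 minus miR-483 on the log2(FPKM + 1) scale, and folds given as N-fold are ratios of mean FPKM. On data simulated for this comparison over 12216 genes, 51 of 100 genes changed by 0.5 log2 and 91 of 100 changed by 1 log2 were recovered, with 9 false calls among 151. Only 200 genes were changed in the simulation, far fewer than were called in the data. Because the adjustment depends on that share, the simulated recovery does not give the recovery in the real fit.

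Gene lists, 27 in number, were fixed before the data were examined, and 26 had a tested member. They covered reported miR-483 targets, the miR-483 host locus, microRNA machinery, endothelial identity, nitric oxide and KLF2/KLF4, NF-κB, interferon, NRF2, oxidised base repair, S phase, G2/M, TGF-beta, matrix, Notch and tip cell, cholesterol, stress responses, p53, hypoxia, immediate early, oxidative phosphorylation, ribosome and mitochondrial genes, and markers of mural, leukocyte, erythroid, epithelial and lymphatic cells. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. List members with other names were matched through older symbols, and members without a row were not analysed here. The named genes followed a rule fixed at the same time: an adjusted p of at most 0.05, an average of at least 2 (here log2(FPKM + 1) in place of log2 CPM), groups that do not overlap, and then the 12 largest rises and 12 largest falls, leaving out unnamed, noncoding, XIST and Y-linked genes, plus IGF2, up to 6 reported targets and up to 4 genes per list with the smallest p. Some genes that meet this rule are not reported here.

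For the seed sites, the longest annotated 3′ UTR per gene was taken from GENCODE 29, and names were matched by symbol. That annotation is on another build than the files, so only sequences and lengths were used and no coordinates. Both mature arms, AAGACGGGAGGAAAGAAGGGAG (5p) and TCACTCCTCTCCTCCCGTCTT (3p), were found in the 76 nt MIR483 hairpin. Sets of 7-mer matches were tested with camera among genes with a UTR and set against up to 200 control 7-mers with the same bases and number of CpG. Figures were drawn in matplotlib from Python 3.11.15. Alternatives covered the pseudocount, filters, a replicate block, each library left out, scaling, repeated names, a fold threshold, other site lengths and the shortest UTR.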

Results

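Gene expression was profiled by RNA sequencing in human umbilical vein endothelial cells (HUVECs), primary cells that line the vein of the umbilical cord. The cells had been transfected with the microRNA miR-483 (3 libraries) or with 8OH-G miR-483, a form of it that carries the oxidised base 8-oxoguanine (3 libraries), and total RNA was taken on day 2. The question posed by the design was whether the oxidised form changes the set of messenger RNAs that the microRNA acts on. A scramble control is named in the labels' protocol and was not analysed here, so every difference below is one between the 2 groups and can come from either microRNA form. A difference in culture or handling between the groups, if there was one, cannot be told apart from the form. The labels do not say which arm of miR-483 was used or which guanine was oxidised. The deposited values were taken as FPKM, inferred from their size, with totals from 1396537 to 1687283 per library. Read depth is unknown, so no counting interval is given. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

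The cells given 8OH-G miR-483 had higher levels of cell-cycle genes and of the chemokine genes CXCL8 and CXCL1, and lower levels of the endothelial transcription factors KLF2 and KLF4, of a laminin-binding integrin subunit and of cholesterol synthesis genes. The interleukin-8 gene CXCL8 rose from 1.30 ± 0.523 to 30.3 ± 6.18 FPKM (mean ± SD, n = 3 libraries per group throughout). KLF2, which is induced by blood flow and maintains the quiescent endothelial state, fell from 175 ± 3.14 to 14.0 ± 2.47 FPKM. ITGB4, the integrin β4 subunit of laminin receptors, fell from 312 ± 11.6 to 8.27 ± 0.533 FPKM, a 37.7-fold lower mean. With limma on log2(FPKM + 1), 6772 of 12216 genes passed an adjusted p of 0.05, of which 4279 were higher and 2493 lower with 8OH-G miR-483. The fitted change on the log2(FPKM + 1) scale was at least 1 in size for 659 of the higher and 318 of the lower genes, and for 946 and 487 with a pseudocount of 0.1. The higher genes made up 63.2% of the calls as deposited, but 50.1% after median-ratio scaling and 49.0% after quantile normalization, which moved the median log2 fold change of all genes by -0.10 and -0.11. With a fold threshold of 1.2 in the test, 3311 genes passed.

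Among the 12 genes with the largest rises, 6 belonged to the fixed S phase and G2/M lists: RRM2, MCM4, MCM2, UHRF1, CLSPN and CDC20. RRM2, a subunit of ribonucleotide reductase, went from 5.99 ± 0.436 to 47.7 ± 5.94 FPKM. The replicative helicase subunits MCM4 and MCM2 rose 7.79-fold and 8.71-fold in mean FPKM. CXCR4, the receptor of the chemokine CXCL12, rose from 6.34 ± 1.14 to 53.5 ± 14.0 FPKM. IL1RL1, the interleukin-33 receptor, rose from 8.21 ± 1.68 to 52.8 ± 14.2 FPKM. DKK1, a secreted Wnt inhibitor, rose 6.13-fold and RGS4, a regulator of G-protein signalling, rose 5.82-fold. The neutrophil chemokine CXCL1 rose 9.09-fold in mean FPKM. CXCL1 is close in sequence to CXCL2 and CXCL3, so its level is uncertain where reads could be shared. In limma, the log2 fold changes of these 12 genes ran from 2.39 (CXCL1, SE 0.145) to 3.78 (CXCL8, SE 0.182), on the log2(FPKM + 1) scale, which understates the change of low genes.

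Among the 12 genes with the largest falls, ITGB4 was followed by the peptidase inhibitor gene PI16, which went from 27.4 ± 4.21 to 0.185 ± 0.0177 FPKM. LCN6, a lipocalin, fell from 32.5 ± 2.45 to 0.809 ± 0.0539 FPKM, and GDF3, a TGF-beta family ligand, from 34.5 ± 3.19 to 1.47 ± 0.492 FPKM. The tartrate-resistant acid phosphatase gene ACP5 fell from 116 ± 32.6 to 8.88 ± 3.94 FPKM. KLF4 fell from 17.5 ± 1.46 to 1.06 ± 0.0502 FPKM. ENTPD1, the ectonucleotidase CD39 that clears extracellular ATP and ADP, fell 9.05-fold, PTHLH (parathyroid hormone-like hormone) 8.79-fold, the prohormone-processing enzyme CPE 8.35-fold and the sialyltransferase gene ST8SIA6 10.9-fold. AKR1C1, an aldo-keto reductase with near-identical relatives, went from 13.1 ± 1.62 to 0.572 ± 0.236 FPKM and is uncertain where reads could be shared. In limma, the log2 fold changes of these 12 ran from -5.08 (ITGB4, SE 0.068, adjusted p = 5.44e-09) to -2.87 (ST8SIA6, SE 0.123, adjusted p = 1.22e-06). In all 24 genes the 3 values of one group lay outside those of the other, a pattern that was part of the rule by which they were chosen.

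**Figure D1:**
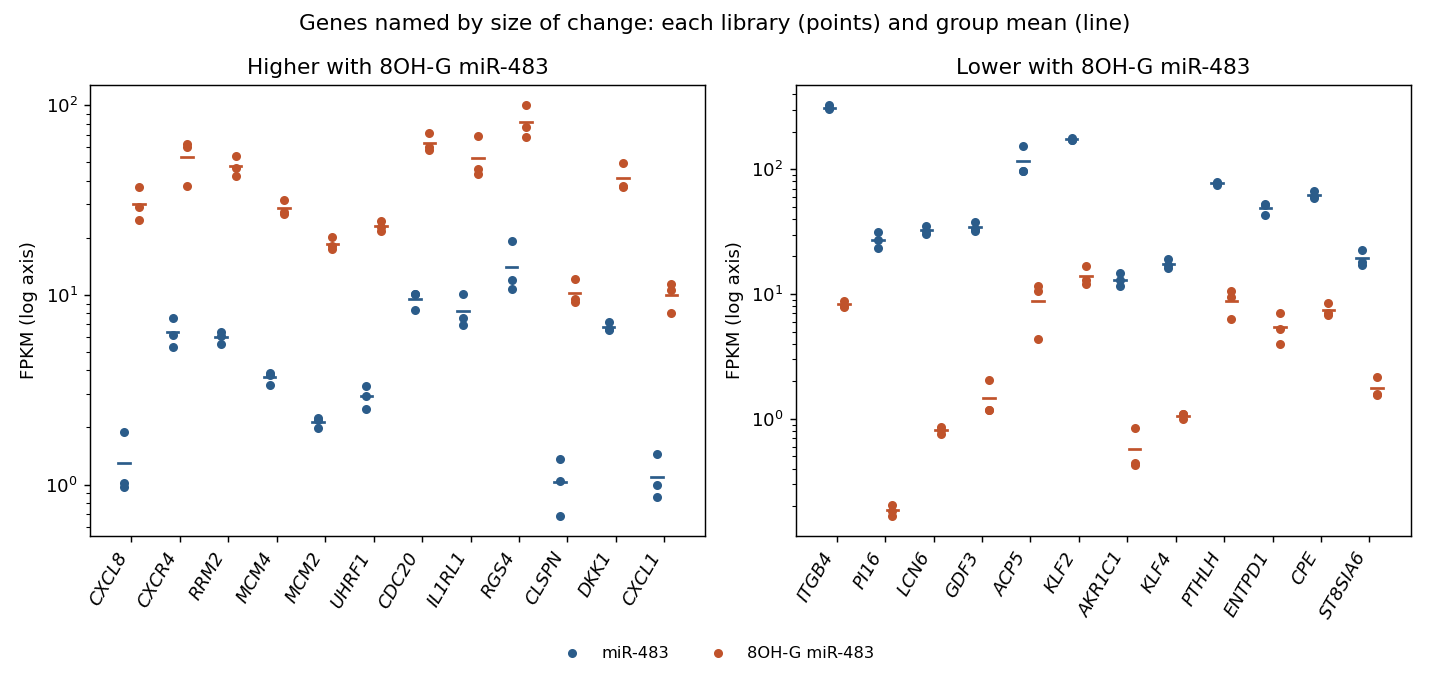
FPKM on a log axis for the 12 genes with the largest rises (left) and the 12 with the largest falls (right), with 1 point per library and a line at the mean of each group of 3. ITGB4 lies at a mean of 312 FPKM with miR-483 and 8.27 FPKM with 8OH-G miR-483, and in each of the genes the groups do not overlap.

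The proliferation lists moved as blocks. All 27 tested G2/M genes rose, with a median log2 fold change of 2.01 and an interquartile range of 1.82 to 2.15, and all 23 S phase genes rose, with a median of 1.91. CDK1, the mitotic kinase, rose from 6.15 ± 0.285 to 33.8 ± 2.54 FPKM, the ubiquitin-conjugating enzyme gene UBE2C from 8.96 ± 0.132 to 48.7 ± 3.02 FPKM and cyclin A2 (CCNA2) from 4.07 ± 0.0855 to 20.1 ± 2.42 FPKM. The counts were again 27 and 23 when adjusted over the list alone. Against all other genes, camera with its preset correlation gave an adjusted p of 1.03e-13 for G2/M and 1.92e-12 for S phase. With an estimated correlation, both lists had an adjusted p = 0.45, so neither call held.

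Genes of nitric oxide production and of the KLF2 and KLF4 response fell in 10 of 11 tested cases. Besides KLF2 and KLF4, ASS1, which recycles citrulline to arginine, fell from 4.82 ± 0.696 to 0.372 ± 0.129 FPKM and the hedgehog ligand gene DHH from 7.81 ± 0.563 to 1.78 ± 0.208 FPKM. NOS3, the endothelial nitric oxide synthase, fell from 160 ± 10.8 to 66.1 ± 2.18 FPKM. The exception was HSP90AA1, a chaperone that binds NOS3, which rose from 179 ± 4.68 to 359 ± 30.5 FPKM. The list's median log2 fold change was -0.88, with a camera adjusted p of 4.95e-06 and an adjusted p = 0.35 with an estimated correlation. It held 10 lower genes and 1 higher when adjusted over the list alone. Of 23 tested endothelial identity genes, 13 fell, 1 rose (ICAM2) and 9 did not pass, both over all genes and, as 13 lower and 1 higher, adjusted over the list alone. The angiopoietin receptor TEK fell 3.58-fold to 24.1 ± 0.476 FPKM, the sialomucin EMCN 3.11-fold, the diaphragm protein PLVAP 2.97-fold and MMRN1 2.49-fold. The junction and adhesion genes PECAM1 (219 ± 5.82 to 122 ± 18.3 FPKM) and CDH5 (381 ± 8.96 to 268 ± 20.8 FPKM) and the von Willebrand factor gene VWF (509 ± 12.2 to 243 ± 35.3 FPKM) also fell, while KDR, the main VEGF receptor, had levels of 62.6 ± 0.799 and 62.0 ± 7.46 FPKM (adjusted p = 0.859, limma). The endothelial list had a median of -0.45, a camera adjusted p of 2.86e-05 and an adjusted p = 0.45 with an estimated correlation. NOS3, PECAM1, CDH5, VWF, KDR, HSP90AA1 and ICAM2 were picked after their values were seen.

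Of 22 tested cholesterol synthesis and uptake genes, 17 fell and 1 rose, with the same counts adjusted over the list alone. HMGCS1, an early enzyme of the pathway, fell from 15.7 ± 1.60 to 6.10 ± 0.188 FPKM, INSIG1 from 24.0 ± 0.441 to 10.1 ± 0.327 FPKM and SREBF2, the transcription factor that drives the pathway, from 30.4 ± 0.689 to 16.0 ± 0.747 FPKM. The median log2 fold change was -0.63. Camera gave an adjusted p of 2.49e-07, and an adjusted p = 0.44 with an estimated correlation.

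The remaining lists went both ways or did not pass camera, with adjusted p from 0.119 to 0.972 over 26 lists tested. Over all 12216 tested genes, 4279 rose and 2493 fell, and the counts below are to be read against that background. In the NF-κB inflammatory list, 6 of 13 genes rose, among them CXCL8, CXCL1 and the granulocyte factor gene CSF3 (0.653 ± 0.0623 to 3.27 ± 0.470 FPKM), and 4 fell, among them NFKBIA, the inhibitor of NF-κB (70.7 ± 5.67 to 24.6 ± 3.58 FPKM). Of these 13 genes, 7 were higher and 4 lower when adjusted over the list alone. In the Notch and tip cell list, 7 of 18 rose and 3 fell. Its tip cell genes ESM1 (28.7 ± 1.56 to 104 ± 11.4 FPKM) and APLN (79.4 ± 8.21 to 206 ± 2.52 FPKM) and the Notch ligand JAG1 (10.3 ± 0.658 to 25.2 ± 1.55 FPKM) rose with CXCR4. In the NRF2 antioxidant list, 10 of 21 rose, with HMOX1, heme oxygenase 1, up 2.83-fold and OSGIN1 up 1.98-fold, and 6 fell, among them AKR1C1 and AKR1B1 (1.77-fold lower mean). Of 14 genes for the repair or clearance of oxidised bases, 9 rose and 2 fell, or 7 and 3 after median-ratio scaling and 7 and 2 after quantile normalization. PNPT1, a mitochondrial RNA nuclease, rose 2.43-fold and APEX1, an apurinic site endonuclease, 2.04-fold, while the glycosylases NTHL1 and NEIL1 were 1.69-fold and 1.59-fold lower.

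Of 21 genes of the integrated stress and unfolded protein responses, 10 rose and 6 fell. The 4 with the smallest p, SLC7A5, PSAT1, PHGDH and ASNS, all act in amino acid uptake or synthesis and rose 4.74-fold, 3.46-fold, 3.23-fold and 2.51-fold. Of 19 hypoxia and glycolysis genes, 8 fell and 4 rose. NDRG1 fell from 58.9 ± 1.11 to 16.3 ± 2.14 FPKM, the demethylase gene KDM3A 2.08-fold and the glucose transporter gene SLC2A1 1.75-fold, while hexokinase 2 (HK2) rose 2.79-fold. Among 10 immediate early genes, 5 rose, with MYC from 26.2 ± 0.943 to 49.5 ± 1.91 FPKM, FOSL1 2.37-fold and JUN 1.63-fold higher and EGR1 from 0.102 ± 0.0549 to 1.97 ± 0.207 FPKM, and 4 fell. Of 21 p53 targets, 4 rose and 6 fell, or 3 and 9 after either median-ratio scaling or quantile normalization. GDF15, a stress cytokine, rose 2.08-fold and AEN 1.31-fold, and the proapoptotic BBC3 was 2.53-fold and TP53INP1 1.82-fold lower. Of 23 TGF-beta and mesenchymal transition genes, 10 rose and 3 fell, as deposited, and 7 rose and 5 fell after median-ratio scaling. CDH2, N-cadherin, rose 2.22-fold and ZEB2 1.58-fold, and SMAD7, the inhibitory SMAD, fell 3.34-fold. Of 22 matrix genes, 7 rose and 9 fell, or 4 and 10 after median-ratio scaling, with NID1, MMP2 and ADAMTS4 lower by 1.86-fold, 1.74-fold and 2.31-fold and TIMP1 down from 128 ± 7.69 to 85.5 ± 6.34 FPKM. In the interferon list, 5 of 19 rose, among them IFI44 (2.02-fold), and 8 fell, among them OAS1 (2.34-fold), XAF1 (2.07-fold) and IFITM1 (1.65-fold). Its adjusted p of 0.119 was 0.041 when repeated gene names were included, and without them the adjusted p = 0.45 with an estimated correlation. Adjusted over the list alone, the higher and lower counts were 11 and 6 for the stress responses, 4 and 8 for hypoxia, 5 and 4 for immediate early, 4 and 6 for p53, 10 and 3 for TGF-beta, 7 and 9 for matrix, 5 and 9 for interferon, 7 and 3 for Notch, 11 and 7 for NRF2 and 9 and 2 for oxidised base repair.

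Of 26 oxidative phosphorylation genes, 8 rose, among them NDUFS1 (1.96-fold), NDUFS3 (1.60-fold), SDHB (1.47-fold) and ATP5B (1.35-fold), and 0 fell, whereas after median-ratio scaling 6 rose and 2 fell. Of 32 cytosolic ribosome genes, 3 rose, among them RPL35 and RPL10A, and 1 passed when adjusted over the list alone. After median-ratio scaling 1 rose and the list median of 0.09 became -0.02, and after quantile normalization 8 rose. RPL10A did not pass after that scaling (adjusted p = 0.0994), nor without miR-483 replicate 1 (0.0853), miR-483 replicate 3 (0.0749) or 8OH-G miR-483 replicate 2 (0.071). Of 11 mitochondrial transcripts, 5 rose and 0 fell as deposited, 3 rose and 3 fell after median-ratio scaling, and 2 rose and 0 fell after quantile normalization. One of them, MT-ND4L, held 60.8% to 67.2% of all FPKM in a library, and its level and that of MT-ATP8 were treated as unreliable. Of 13 microRNA machinery genes, 6 rose, among them the export receptor gene XPO5 (1.91-fold) and DROSHA (1.58-fold), and AGO4 fell 1.53-fold, whereas 3 rose and 1 fell after either scaling. Adjusted over the list alone, the higher and lower counts were 8 and 0 for oxidative phosphorylation, 5 and 0 for mitochondrial transcripts and 7 and 1 for microRNA machinery.

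Markers of other cell types were few. Of 3 tested leukocyte markers, 2 fell: LYZ from 4.03 ± 0.339 to 0.109 ± 0.0955 FPKM and CD68 from 11.9 ± 1.85 to 7.15 ± 0.760 FPKM, and LAPTM5 was at 38.8 ± 3.22 and 40.2 ± 1.58 FPKM. Of 2 mural and fibroblast markers, COL3A1 fell from 2.33 ± 0.0651 to 1.26 ± 0.0851 FPKM and MCAM, also made by endothelium, was at 438 ± 26.1 and 465 ± 31.0 FPKM. Of 3 lymphatic endothelial markers, LYVE1 fell from 22.5 ± 1.62 to 13.5 ± 2.48 FPKM and PROX1 from 4.98 ± 0.677 to 3.48 ± 0.821 FPKM, and FLT4 did not pass. Of 4 epithelial markers, KRT18 rose from 61.1 ± 3.76 to 120.5 ± 7.83 FPKM and GATA3 from 9.13 ± 0.518 to 10.6 ± 0.461 FPKM, while KRT8 and KRT19 did not pass. The GATA3 call was lost after median-ratio scaling (adjusted p = 0.317) and without miR-483 replicate 2 or 3 or any 8OH-G miR-483 replicate (0.0506 to 0.129), and that of PROX1 without miR-483 replicate 1 (0.109), miR-483 replicate 2 (0.054) or 8OH-G miR-483 replicate 2 (0.0674). KRT19 passed without 8OH-G miR-483 replicate 1 (0.0159) and FLT4 without 8OH-G miR-483 replicate 3 (0.0108). Adjusted over the list alone, 2, 1, 2 and 3 markers passed in these 4 lists. No erythroid marker was analysed here.

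**Figure D2:**
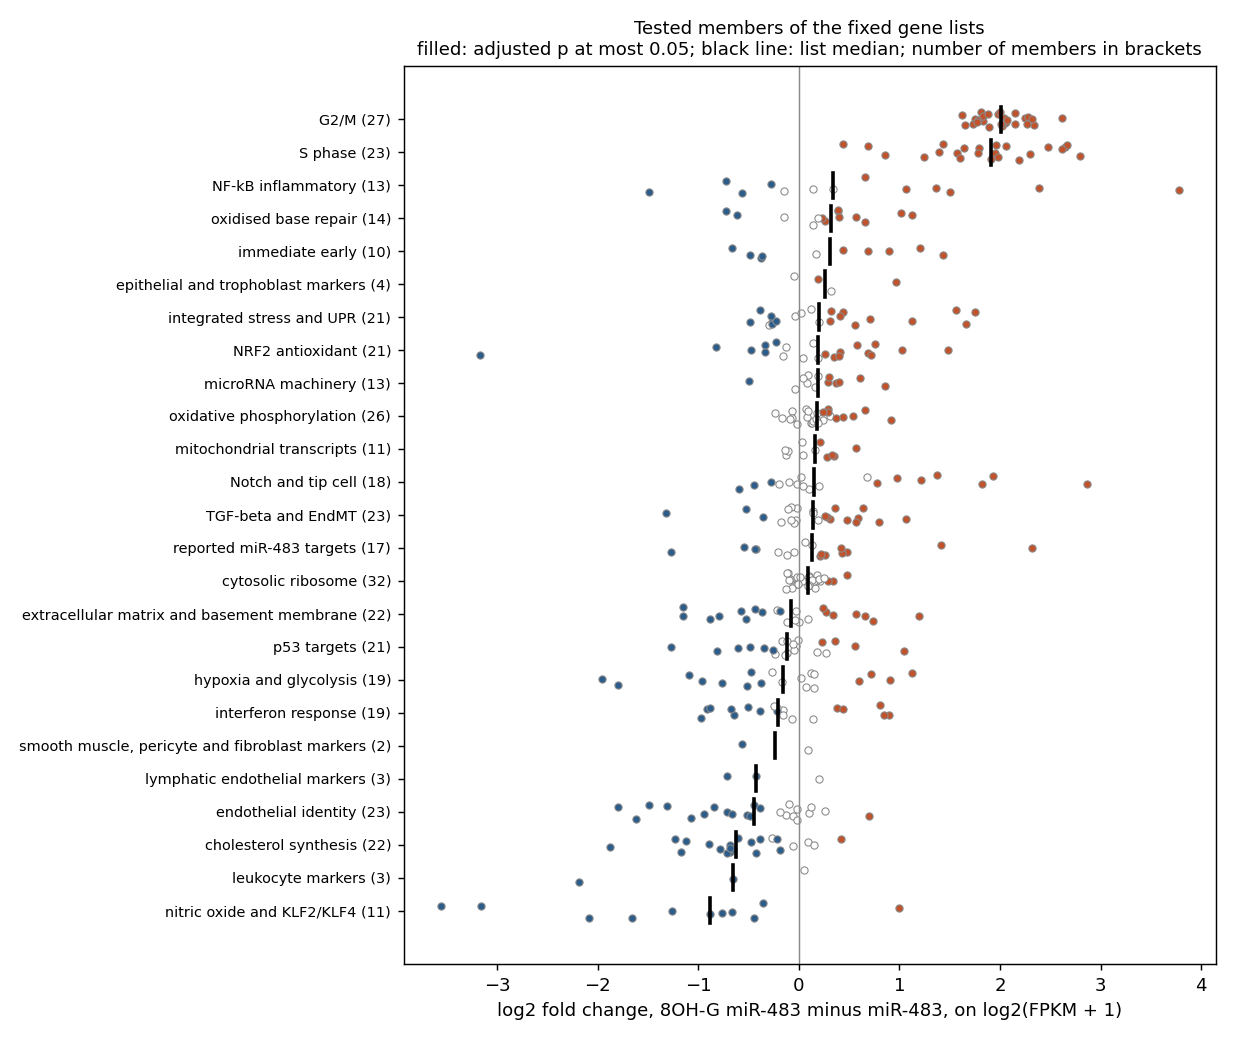
Log2 fold change (8OH-G miR-483 minus miR-483, on log2(FPKM + 1)) of each tested member of the fixed lists with more than 1 tested gene, with filled points at an adjusted p of at most 0.05 in limma and a black line at each list median. The G2/M and S phase medians lie at 2.01 and 1.91 and the nitric oxide and KLF2/KLF4 median at -0.88.

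Of 17 tested genes reported elsewhere as miR-483 targets, 8 rose, 4 fell and 5 did not pass, with a median log2 fold change of 0.13. Against other genes, camera gave an adjusted p of 0.972, while fry, which does not compare a list with other genes, called it higher (adjusted p = 0.000459). After median-ratio scaling, 5 rose and 6 fell. The largest rises were those of UBE2C, which is also in the G2/M list, and of the cell-cycle phosphatase gene CDC25A (1.59 ± 0.0960 to 5.92 ± 0.632 FPKM). Connective tissue growth factor (CTGF) rose from 315 ± 5.58 to 440 ± 27.9 FPKM. BBC3 fell from 27.2 ± 2.14 to 10.8 ± 1.63 FPKM, MAPK3 from 95.1 ± 11.7 to 64.4 ± 1.30 FPKM and TIMP2 from 142 ± 2.36 to 105 ± 7.49 FPKM. Adjusted over the list alone, 8 were higher and 4 lower. IGF2, the gene whose intron holds the miR-483 hairpin, fell from 32.9 ± 4.62 to 6.08 ± 0.841 FPKM, a log2 fold change of -2.26 (SE 0.122, adjusted p = 2.85e-06, limma).

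The seed-site comparison asked whether genes whose 3′ UTR holds a match to a miR-483 seed differed from genes without one. Of 10497 tested genes with an annotated 3′ UTR, 896 held CCCGTCT, the match to seed positions 2 to 8 of the 5p arm. Of these, 317 rose and 187 fell, and their mean log2 fold change lay -0.011 from that of genes without the match (camera adjusted p = 0.858). The SE of 0.018 is taken over the genes with the match alone and leaves out the spread between libraries. The 5p seed has 4 guanines, and 8-oxoguanine can pair with adenine, so sites with adenine opposite each of them were also searched. Adenine opposite seed position 3 gave 156 genes and a shift of 0.012, position 6 gave 1553 genes and -0.016, position 7 gave 475 genes and -0.080 and position 8 gave 297 genes and -0.018. The position 8 match, ACCGTCT, still holds CCGTCT, a shorter match to the unmodified 5p seed. With adenine opposite all of them, 2245 genes had a shift of 0.057. The 3p seed, which has 0 guanines, matched 1442 genes, with a shift of -0.040. Of the reported targets, MAPK3 and TIMP2, which fell, ARHGDIA, which rose, and ALCAM and FIS1, which did not pass, held the unmodified 5p match. UBE2C, CDC25A, CTGF and BBC3 held none of the 7-mers searched. Among the genes with the largest changes, the unmodified 5p match was held by MCM4, which rose, and KLF2, which fell. None of the 7 sets passed camera at an adjusted p of 0.05 (range 0.782 to 0.858), and the count at an unadjusted p under 0.05 was also 0. Such shifts also depend on base composition: control 7-mers with the bases and the number of CpG of the 5p match had a median shift of -0.096, and 96.6% of the 59 controls were lower than the match itself. With adenine opposite all guanines, the control median was 0.055, close to the shift of 0.057. Control medians were -0.047 for positions 3, 7 and 8, -0.032 for position 6 and -0.036 for the 3p match. The controls were not matched for the number of genes that hold them.

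**Figure D3:**
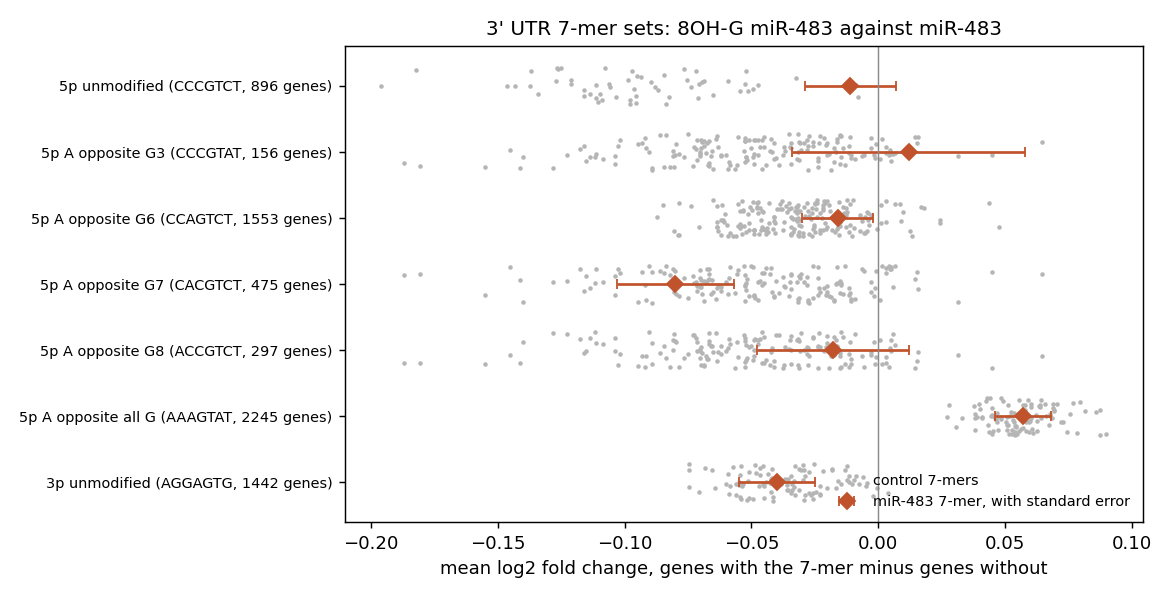
Mean log2 fold change of genes with a 3′ UTR 7-mer minus that of genes without it, for the 7 miR-483 sets (diamonds) and for control 7-mers of the same base composition (grey points). Bars on the diamonds are the standard error over the genes with the 7-mer alone. The unmodified 5p match lies at -0.011, higher than 96.6% of its controls, and the 3p match at -0.040, higher than 45.2% of its controls.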

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

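Chosen after seeing the data were median-ratio scaling, quantile normalization, repeated names, the 5 FPKM filter, the fold threshold and shrinkage without robust. The count of 6772 genes stayed within 1.5 times under each alternative except the fold threshold of 1.2, with 3311 genes (2185 higher, 1126 lower), since that test asks for more than any change. A pseudocount of 0.1 moved the genes with a fitted change of at least 1 log2 from 659 higher and 318 lower to 946 and 487, since the main pseudocount shrinks the change of low genes. Leaving out 1 library gave 5859 to 6479 genes, 3772 to 4104 higher and 2087 to 2375 lower. No gene called in the main fit was called with the opposite sign under any alternative. Of 1971 values for 132 named genes, 1928 kept their side of the threshold, 38 fell below it, 5 newly passed and 0 reversed. Direction was not compared where a gene passed in neither the main fit nor the alternative. The 5 lists passed camera under the block, scaling and each left-out library. With an estimated correlation 0 passed: adjusted p 0.45 for G2/M, S phase and endothelial identity, 0.44 for cholesterol synthesis and 0.35 for nitric oxide and KLF2/KLF4. This alternative of camera also uses fewer degrees of freedom, and the cause was not tested. Fry, which does not compare a list with other genes, passed 24 lists. No seed-site set passed under any alternative. The replicate block gave 7312 genes, 5 lists and 0 seed-site sets, and among markers of other cell types GATA3 did not pass under it (adjusted p = 0.0518) and KRT19 did (0.00848). Deviations of same-numbered libraries correlated at 0.02, 0.34 and 0.01, and not every library correlated best with its own number, so the numbers were not taken as pairs. Size factors in a count model, both other count tests and a count-based fold threshold were not run, since the files hold no counts. A filter of 1 CPM is here the main filter of 1 FPKM. Unknown depth limits what can be said of genes near 1 FPKM.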

Other observations

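The lists in this part, the tests of library scaling and of the number of genes over other splits, and the UTR trend check, which was then also required for the unmodified 5p sites, were chosen after the main results had been seen. Genes that build ribosomes rose as a block. All 21 tested ribosome biogenesis genes were higher with 8OH-G miR-483, with a median log2 fold change of 1.2 (camera adjusted p = 1.58e-09 over 11 added lists, adjusted p = 0.38 with an estimated correlation). Values are mean ± SD (n = 3). Nucleolin (NCL) rose from 109 ± 8.33 to 239.7 ± 23.2 FPKM and NOP56, a core nucleolar RNP protein, from 37.6 ± 3.46 to 91.8 ± 6.77 FPKM. All 7 tested tubulin genes rose, with a median of 0.93 (camera adjusted p = 1.18e-03, 0.38 with an estimated correlation), although tubulins share sequence and their split is uncertain. TUBA1C rose from 51.4 ± 6.75 to 209 ± 25.01 FPKM. In the serine and one-carbon list 7 of 11 rose and 1 fell (camera adjusted p = 0.0925), with the folate enzyme MTHFD1 from 10.9 ± 2.18 to 47.5 ± 3.62 FPKM.

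The coagulation list and the junction and integrin list had members that went both ways. The urokinase gene PLAU and its receptor PLAUR rose from 21.1 ± 1.43 to 58.0 ± 6.52 and from 24.3 ± 2.83 to 65.4 ± 2.67 FPKM, while TFPI, the tissue factor pathway inhibitor, fell from 267 ± 9.68 to 131 ± 7.73 FPKM and protein S (PROS1) from 3.75 ± 0.0897 to 1.60 ± 0.251 FPKM (3 of 10 coagulation genes rose and 2 fell, or 3 and 4 after median-ratio scaling, camera adjusted p = 0.776). ITGA6 and ITGA3, which form laminin receptors, fell from 118 ± 4.23 to 65.0 ± 1.46 and from 55.9 ± 0.730 to 27.1 ± 0.507 FPKM beside the much larger fall of ITGB4 (4 of 11 junction and integrin genes fell, 1 rose, camera adjusted p = 0.109, 0.38 with an estimated correlation, 0.0488 with repeated names). Of 4 uniquely named antigen processing genes, 0 rose and 0 fell (camera adjusted p = 0.728). With repeated names, whose rows differ in miR-483 replicate 1, 6 of 15 fell and 1 rose (camera adjusted p = 0.0187, 0.33 with an estimated correlation), with HLA-E, a repeated name, at 349 ± 19.7 and 132 ± 11.1 FPKM. The actin (11 of 17 higher, 2 lower, camera adjusted p = 0.109), lipid uptake and efflux (4 of 9 lower, 1 higher, 0.0925) and BMP target lists (3 higher and 3 lower of 9, 0.674) did not pass.

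The rise of cell-cycle genes with the fall of KLF2, KLF4 and endothelial genes was weighed first. Scaling of the libraries is argued against, since the G2/M median stayed at 1.91 after median-ratio scaling, with a lower quartile of 1.72. This follows from the small scaling factors (0.957 to 1.046) and is not a separate test. A trend on gene length and GC is argued against as the whole cause, since the G2/M median was 1.77 once it was removed, with -1.02 for nitric oxide and KLF2/KLF4 and -0.38 for endothelial identity. Open are sparser cultures with more YAP/TEAD activity: the YAP/TEAD target median was 0.38 (8 of 13 higher, 1 lower, camera adjusted p = 0.0396, 0.51 with an estimated correlation), but another split of the libraries reached 0.34, and the call was lost without miR-483 replicate 2 (0.0628) or 8OH-G miR-483 replicate 1 (0.0534) or 3 (0.0699). The labels give no culture density, and an effect of the oxidised base itself stays open beside it, as does an effect of unmodified miR-483 that the oxidised form lacks.

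Genes with miR-483 seed matches were weighed next. Loss of repression through unmodified 5p sites met its prediction only in the comparison with control 7-mers and is left undecided. Genes with the match were not higher than genes without it, as loss of repression would require. The shift was -0.011 log2, with median log2 fold changes of 0.104 and 0.113 (camera adjusted p = 0.858). Of control 7-mers, 96.6% lay lower than the unmodified 5p match, and 98.3% did once a trend on UTR length and GC was removed, when the shift was 0.051 log2. For the site with adenine opposite position 3, for which the opposite direction had been predicted, the values were 96.6% and 87.0%. Neither set passed camera. The controls were not matched for how many genes hold them. The unmodified 5p match was in 896 genes. The controls CCGTCTC (1061 genes) and TCCGCCT (829 genes) had shifts of -0.0089 and -0.008, slightly above that of the match. CCGTCTC itself holds CCGTCT, a shorter match to the unmodified 5p seed, so it is not free of a miR-483 site. TCCGCCT does not hold it, so how common a 7-mer is can still not be told apart from repression. Repression through sites with adenine opposite an oxidised guanine is left undecided, since the lowest such set, at position 7, lay above 18.6% of its controls. The sets at position 6, at position 8 and at all guanines lay above 76%, 76.8% and 55.8% of theirs, against the predicted direction. Different dosing through the 3p seed is undecided as well, at 45.2% of controls.

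KLF2, KLF4 and TSC22D3 (19.3 ± 1.26 to 3.91 ± 0.622 FPKM) fell together with 8OH-G miR-483. Lower FOXO activity is a candidate explanation, since FOXO factors can induce them. Whether FOXO factors drive them in these cells was not tested, nor were other shared regulators. Other FOXO targets had a median of -0.26, with 7 of 14 lower and 3 higher (camera adjusted p = 0.0396, 0.45 with an estimated correlation, 0.0677 after median-ratio scaling, 0.0571 without 8OH-G miR-483 replicate 3). PIK3IP1 fell from 6.15 ± 0.387 to 1.98 ± 0.449 FPKM and TXNIP from 2.20 ± 0.293 to 0.355 ± 0.0709 FPKM, while GADD45A rose from 11.9 ± 1.32 to 32.8 ± 7.76 FPKM. The hypothesis remains open and rests on a list with members that went both ways.

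The 6 libraries split 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 6772 genes (1 split with as many) against at most 1 in any other. For the 5 lists that passed camera all 10 splits gave as many, up to 8 in another split, so the number of lists past the threshold does not set the real split apart. Each other split mixes the groups, so smaller changes there follow from the design. For seed-site sets the real split gave 0, so that all 10 splits gave as many, and another split gave up to 6.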
